A study of Caenorhabditis elegans with 4 samples.

How the data were processed

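Chromatin from formaldehyde-crosslinked, sonicated late embryos was immunoprecipitated with anti-GFP serum or anti-H3K4me3 antibody and sequenced as Illumina libraries, per the labels' protocols. The authors aligned the reads with BWA to genome build ce10 and called peaks with MACS2 version 2.0.10, per the submitters' processing notes. The deposited files are 4 peak lists, 1 per sample and not pooled, with the chromosome, start, end, name and score of each peak. The aligner's settings, the control used for peak calling, the duplicate treatment and the threshold are not given in the sources used here. The deposited score is in −log10 units of a p-value or q-value; which of these it is, is not given in the sources used here. The lowest scores lie between 1.30 and 1.41, near −log10 of 0.05. The score is the peak's own value from the authors' peak caller. It rises with read depth and with peak width, so it was ranked and tested only within a list, and scores from different lists stand side by side as values without a test. The peak names in the files carry a larval stage abbreviation, whereas all labels give late embryos; the labels were followed. The last peak end over the 4 lists served as the length of each chromosome; it was not checked against the build, for which no lengths were used here.

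Peaks of the RC03 and RC04 lists of an antibody were merged where they shared at least 1 bp, and a merged interval with peaks of both lists was called a region. The score of a region was the mean over both lists of the percentile rank of its highest peak. Overlap between sets was counted at 1 bp or more. Chance overlap was estimated by 1000 circular shifts, in which all intervals of a chromosome move by 1 random distance, which keeps their widths and spacing; 100 shifts were used for deciles and scores. Differences in score or width between regions with and without the other antibody were tested by permutation with 100000 resamples (two-sided). Chromosome densities were tested with exact binomial tests and shares with Fisher's exact test, both two-sided, and adjusted by the Benjamini-Hochberg method within each family of 4. Exact binomial (Clopper-Pearson) intervals are at 95% and cover counting error only. An exact permutation test over the 4 lists, 2 against 2, cannot give a two-sided p under 0.333, so it was run only on the X and centre density ratios; all other p-values refer to regions and their positions. Read depth per sample is unknown, so no precision could be derived from it.

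Regions named in the text were set by a rule fixed before the data were examined: the 5 shared regions with the highest mean percentile rank over the 4 lists, the 5 highest CFP-1 regions without any H3K4me3 peak, the 5 highest H3K4me3 regions without any CFP-1 peak, and the 3 widest H3K4me3 regions. Positions are given 1-based in ce10. CpG density, distance to transcript starts and gene lists had been planned under the condition of a reference in the same build. The gene table at hand is of assembly WBcel235, and no genome sequence was used here, so these parts were not run and no region was assigned to a gene.

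Alternatives planned beforehand were stricter overlap (50% of the shorter or of both intervals), the 50% of each list with the higher scores, all merged peaks of either list, each list left out in turn, lists compared by sample number, covered base pairs in place of region counts, and the central 50% of the autosomes. Alternatives added later allowed a gap of up to 500 bp, counted any peak of either list of the other antibody, repeated the width comparison in the higher-scored regions, and gave the region counts under the planned settings. The overlap code gave the same counts as bedtools 2.31.1 on the CFP-1 regions (5427 of 7577 at 1 bp). It was tested on simulated data: a simulated set of 7577 intervals with 60% overlap returned 60.0%. Of 100 sets made by circular shifts of the CFP-1 regions, 5 had a p under 0.05. These sets were made by the same kind of shift that the test uses, so this rate was largely fixed in advance. It checks the code and not the fit of the shifts to unrelated features. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.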

Results

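ChIP-seq peak lists were available from late embryos of the nematode Caenorhabditis elegans, aged for 3.5 hours after collection. The embryos came from strain JA1597, which carries a single-site transgene that expresses GFP-tagged CFP-1 from the dpy-30 promoter. CFP-1 is the worm CXXC zinc finger protein, a DNA-binding subunit of the COMPASS complex that methylates histone H3 at lysine 4. Trimethylation of this lysine (H3K4me3) typically marks the promoters of transcribed genes. The design set 2 immunoprecipitations side by side, one with an anti-GFP serum for CFP-1::GFP and one with an anti-H3K4me3 antibody. Each had 2 samples, numbered RC03 and RC04, so the question addressed here is where CFP-1 and the mark were called, and how far their positions coincided. The CFP-1 lists held 9216 peaks in RC03 and 9256 in RC04, a mean of 9236 ± 28.3 (SD, n = 2). The H3K4me3 lists held 11357 and 12343 peaks, a mean of 11850 ± 697 (SD, n = 2). CFP-1 peaks covered 3.08% ± 0.055 (SD, n = 2) of the 100.27 Mb spanned by the 6 nuclear chromosomes, and H3K4me3 peaks covered 6.59% ± 0.056 (SD, n = 2). Read depth is unknown for all 4 lists, because the files give peak positions and scores without read counts. Nothing states that RC03 and RC04 came from separate cultures, so the spread between them may be technical.

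CFP-1 was called at largely the same places in both samples. Of the RC03 peaks, 84.0% overlapped an RC04 peak, and 85.1% of the RC04 peaks overlapped an RC03 peak, against a mean of 6.13% after circular shifts of the peaks along their chromosomes. H3K4me3 peaks were shared at 81.7% from RC03 to RC04 and at 77.9% in the other direction, against 11.2% after shifts. Both values exceeded all 1000 shifts (permutation p = 0.001, the smallest the shifts can give). The peaks that failed to recur were mainly weakly scored ones. Among CFP-1 peaks with a score above their list's median, 99.5% of RC03 and 99.7% of RC04 peaks recurred, against 68.7% and 70.6% of the remaining peaks. The corresponding H3K4me3 values were 99.2% and 97.6% above the median, and 64.4% and 59.0% for the remaining peaks. Merging the lists and keeping intervals called in both samples gave 7577 CFP-1 regions with a median width of 347 bp, and 8050 H3K4me3 regions with a median width of 616 bp. Across these regions the authors' scores in RC03 and RC04 had a Spearman rho of 0.91 for CFP-1 and 0.92 for H3K4me3; regions are not independent replicates. The number of H3K4me3 regions depended on the requirement for both samples, since the RC04 list alone held 12343.

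Most CFP-1 regions lay on H3K4me3. Of the 7577 CFP-1 regions, 5427 overlapped an H3K4me3 region, a share of 71.6% (95% exact binomial interval 70.6 to 72.6%). Circularly shifted CFP-1 regions overlapped H3K4me3 in 10.0% of cases on average and in 14.5% at most, so the observed share was 7.16-fold above the shifted mean (one-sided permutation p = 0.001, the smallest the 1000 shifts can give). From the side of the mark, 5017 of the 8050 H3K4me3 regions overlapped a CFP-1 region, a share of 62.3% (61.3 to 63.4%) against a shifted mean of 9.12% and maximum of 12.9% (one-sided permutation p = 0.001). The 4 pairs of single lists gave 66.5 to 67.1% for CFP-1 peaks on H3K4me3 peaks and 48.1 to 51.1% for H3K4me3 peaks on CFP-1 peaks. A total of 1783 CFP-1 regions had no H3K4me3 peak in either sample, and 2522 H3K4me3 regions had no CFP-1 peak in either sample. Where an overlap of at least 50% of both intervals was required, the shares fell to 10.8% and 10.1%, still above the 1.39% and 1.31% found after shifts. The binomial intervals cover counting error only, and regions are not replicates. Circular shifts also move regions off promoters. They therefore do not separate this overlap from that of other sets placed at promoters. No list from a strain without GFP was analysed here. Anti-GFP signal that does not depend on CFP-1 therefore stays open for these overlaps and for their relation to score.

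The coincidence rose steeply with the score. In the decile of CFP-1 regions with the lowest scores, 43.6% (40.1 to 47.2%) overlapped H3K4me3, and in the decile with the highest scores 95.6% (93.9 to 97.0%) did. The H3K4me3 regions ran from 18.3% (15.7 to 21.1%) with CFP-1 in the lowest decile to 99.6% (98.9 to 99.9%) in the highest, where 802 of 805 regions held a CFP-1 region. The median CFP-1 score was 25.8 in RC03 and 26.4 in RC04 (−log10 units of the authors' peak caller) at regions with the mark, and 8.32 and 8.45 at regions without it. The median H3K4me3 score was 33.3 and 32.8 at regions with CFP-1, and 5.21 and 5.51 at regions without it. A CFP-1 region with the mark outscored one without it with a probability of 0.77, and an H3K4me3 region with CFP-1 outscored one without it with a probability of 0.87 (both two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). Wider regions score higher and are hit more often by chance, and the shifted positions gave probabilities of 0.52 and 0.62, with maxima of 0.55 and 0.65 over 100 shifts. Over the 5427 CFP-1 regions with the mark, the scores of both antibodies, as mean percentile ranks, had a Spearman rho of 0.51 across regions.

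**Figure D1:**
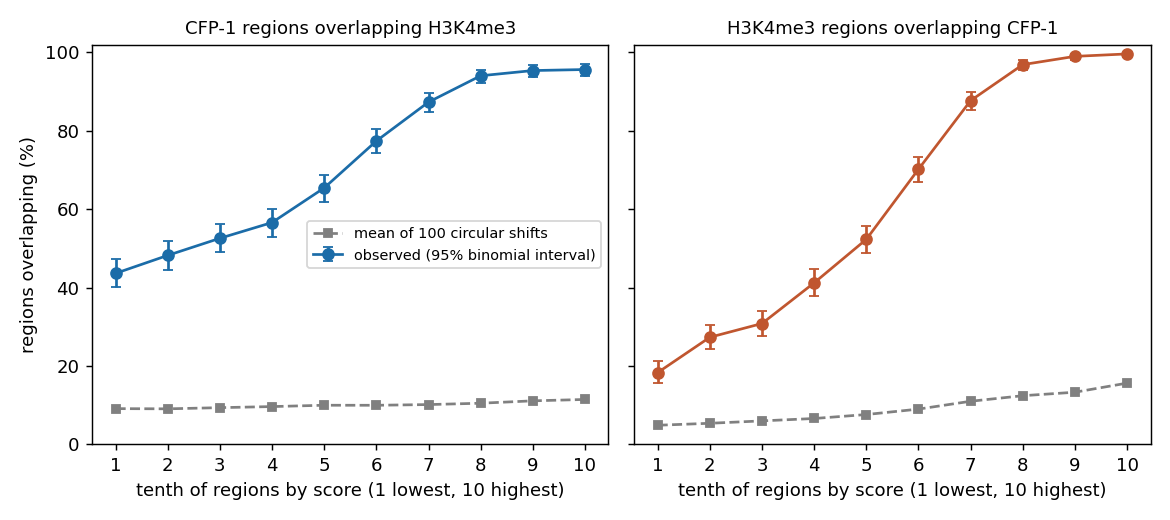
Percent of CFP-1 regions that overlap an H3K4me3 region (left) and of H3K4me3 regions that overlap a CFP-1 region (right), by decile of score from lowest (1) to highest (10). Circles are observed shares with 95% exact binomial intervals and squares the mean of 100 circular shifts; the observed share rose from 43.6% to 95.6% on the left and from 18.3% to 99.6% on the right.

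H3K4me3 regions that held CFP-1 were wider than those without it. The median width was 955 bp (quartiles 516 and 1411 bp) with CFP-1 and 325 bp (quartiles 224 and 505 bp) without it, a difference of 630 bp (two-sided permutation p = 1e-05). Part of such a difference arises because wide intervals are hit more often, and shifted CFP-1 regions gave a mean difference of 449 bp and a maximum of 614 bp, so the observed difference was above all 1000 shifts. Most marked regions with CFP-1 held a single CFP-1 region, 4329 of 5017 or 86.3%, and the most CFP-1 regions found in 1 H3K4me3 region was 8. In 58.2% of the 5904 overlapping pairs the CFP-1 region lay wholly inside the H3K4me3 region, and the midpoints lay a median of 216.5 bp apart. The widest H3K4me3 region, at chromosome II positions 13817110 to 13828746, was 11637 bp wide and held 8 CFP-1 regions. The next widest spanned 11069 bp near the right end of chromosome I (15060283 to 15071351), where the ribosomal RNA gene repeats lie, and coincided with the widest CFP-1 region (15060273 to 15071350). How reads were placed in repeats was not examined for this interval, so its width and scores may not reflect a broad domain. Its H3K4me3 score was 14.0 in RC03 and 36.9 in RC04, and its CFP-1 score was 39.7 and 13.2. The one after that, at chromosome II positions 6827576 to 6836486, held 7 CFP-1 regions.

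**Figure D2:**
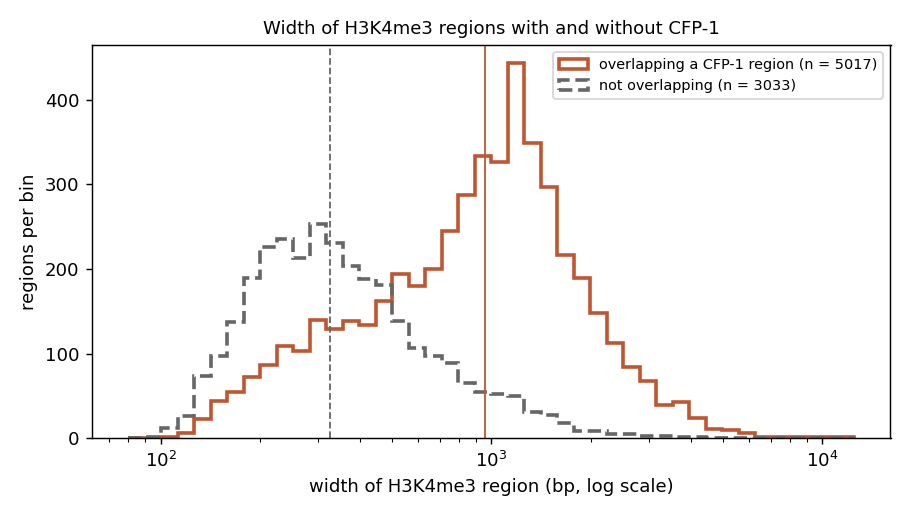
Width of H3K4me3 regions in bp on a log axis, with the number of regions per bin on the vertical axis, for regions that overlap a CFP-1 region (solid, n = 5017) and those that do not (dashed, n = 3033). Vertical lines are the medians, 955 bp and 325 bp.

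The most highly scored regions shared by both antibodies lay on 4 different autosomes. The first, on chromosome III, had CFP-1 at 1201909 to 1202817 with scores of 201.4 in RC03 and 194.1 in RC04, inside an H3K4me3 region at 1201421 to 1203280 with scores of 113.6 and 112.2. The others had CFP-1 at 2387999 to 2389375 on IV, 14154119 to 14154838 on II, 5183541 to 5184267 on IV and 10896796 to 10897578 on V, with CFP-1 scores between 174.0 and 220.6. Some CFP-1 regions of similar strength had no H3K4me3 peak in either sample. The strongest of these lay on V (1917892 to 1918425), with CFP-1 scores of 196.1 and 196.8, and on I (4171936 to 4172503), with 170.9 and 189.9. The next 3 all lay on X, at 806464 to 806902, 14525454 to 14526170 and 4208950 to 4209456, with scores between 149.1 and 181.9. The reverse case was rare among strong H3K4me3 regions. A region on chromosome II (3934790 to 3935618) had H3K4me3 scores of 112.4 and 90.6, a mean percentile rank of 99.0, and no CFP-1 peak. The H3K4me3 regions without a CFP-1 peak that came next, on III (11371382 to 11371755), I (2392998 to 2393406), X (16509119 to 16509928) and II (12184491 to 12185309), had mean percentile ranks of 84.7 to 89.1. All positions are in build ce10, and the genes at these positions were not analysed here.

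CFP-1 and H3K4me3 were unevenly spread over the chromosomes. CFP-1 regions were densest on chromosome I, at 100.05 per Mb, followed by III at 92.9, II at 79.8, IV at 71.5, X at 68.7 and V at 52.7 per Mb. H3K4me3 regions were also densest on I, at 99.7 per Mb, and sparsest on V, at 60.2 per Mb, with X at 78.8 per Mb. The X to autosome density ratio was 0.89 for CFP-1 (95% interval 0.84 to 0.95; exact binomial p = 0.00021, Benjamini-Hochberg adjusted over 4 density tests 0.00028) and 0.98 for H3K4me3 (0.92 to 1.04; exact binomial p = 0.447, adjusted 0.447). Among peaks with a score above their list's median, both antibodies had a ratio below 1, 0.86 (0.79 to 0.94) for CFP-1 and 0.90 (0.83 to 0.97; exact binomial p = 0.0052) for H3K4me3. In single lists the ratio was 0.91 and 0.94 for CFP-1 and 0.98 and 0.99 for H3K4me3. The difference between the antibodies over the 4 lists gave an exact permutation p of 0.333 (two-sided), the smallest this design allows. X nevertheless ranked the second lowest of the 6 chromosomes for CFP-1 and the third lowest for H3K4me3, within the range of the autosomes, so the test treats as even a density that varies between autosomes. X held 16.1% of CFP-1 regions and 17.3% of H3K4me3 regions, an odds ratio of 0.91 (0.84 to 0.99; Fisher's exact test, two-sided p = 0.034, adjusted over 4 Fisher tests 0.045). Within the RC03 lists the odds ratio was 0.92 (Fisher's exact p = 0.035) and within the RC04 lists 0.95 (Fisher's exact p = 0.161), which did not pass the threshold. These tests between the antibodies treat both sets as independent, although 5427 CFP-1 regions overlapped an H3K4me3 region. Their p-values and intervals are therefore approximate. CFP-1 regions overlapped H3K4me3 in 68.6% of cases on X and 72.2% on autosomes (Fisher's exact p = 0.011, adjusted 0.023), with 67.4% on IV and 67.7% on V. H3K4me3 regions overlapped CFP-1 in 58.3% of cases on X and 63.2% on autosomes (Fisher's exact p = 0.00074, adjusted 0.003), with 57.5% on II and 55.1% on V.

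On the autosomes, both antibodies gave denser regions in chromosome centres than in arms. The density in the central 33.3% of each autosome was 1.19 times that of the outer parts for CFP-1 (95% interval 1.13 to 1.25; exact binomial p = 1.8e-11, adjusted 3.6e-11) and 1.22 times for H3K4me3 (1.16 to 1.28; exact binomial p = 9.7e-15, adjusted 3.9e-14). The ratio was above 1 on all 5 autosomes for both antibodies. For CFP-1 it ran from 1.05 on IV (interval 0.93 to 1.18) to 1.36 on V (1.20 to 1.53), and for H3K4me3 from 1.13 on II (1.01 to 1.26) to 1.31 on IV (1.16 to 1.47). On I the CFP-1 ratio was 1.11 (0.99 to 1.23), so its interval included 1, as on IV. The binomial tests treat regions as independent draws, so their p-values do not measure the spread between autosomes. Over the 4 lists the mean ratios were 1.19 ± 0.016 (SD, n = 2) for CFP-1 and 1.16 ± 0.0028 (SD, n = 2) for H3K4me3. Their difference between the antibodies gave an exact permutation p of 0.333 (two-sided), again the smallest possible. That test does not compare centres with arms. In regions the order of the antibodies was the reverse, 1.19 for CFP-1 and 1.22 for H3K4me3. The centre shares of both antibodies, 37.3% and 37.9%, had an odds ratio of 0.98 (0.91 to 1.05, Fisher's exact p = 0.55). This test too treats overlapping regions of both antibodies as independent.

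**Figure D3:**
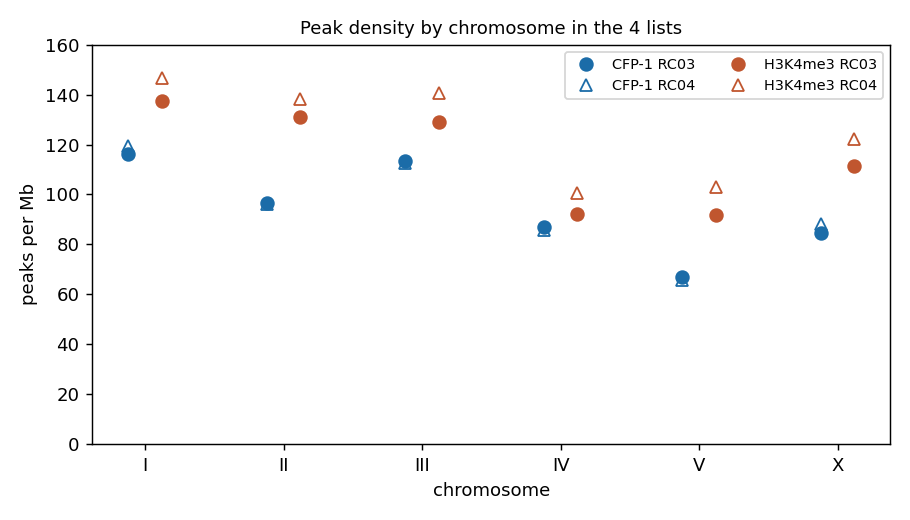
Peaks per Mb on each of the 6 nuclear chromosomes in the 4 lists, CFP-1 in blue and H3K4me3 in orange, RC03 as filled circles and RC04 as open triangles. In the CFP-1 lists the density was highest on I (116 and 120 per Mb) and lowest on V (66.9 and 65.8 per Mb).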

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

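The test of the odds ratio between the antibodies in the higher-scored regions was chosen after the values had been seen. The X chromosome held a smaller share of CFP-1 regions than of H3K4me3 regions, an odds ratio of 0.91. It was singled out because the difference between the antibodies passed Fisher's exact test, which treats overlapping regions as independent. That difference was not seen by covered base pairs, where the X to autosome ratio was 0.895 for both CFP-1 and H3K4me3, nor clearly with all merged peaks, at 0.95 and 0.96. Shorter H3K4me3 regions on X lower the ratio of the mark by covered base pairs. The lower X density of CFP-1 was not confined to weak calls: among peaks with a score above their list's median, the X to autosome ratio was 0.86 (0.79 to 0.94), which argues against weak regions near the peak caller's limit as the whole cause. H3K4me3 had a ratio of 0.90 (0.83 to 0.97) among these peaks, so the mark was also less dense on X there. The odds ratio between the antibodies moved from 0.91 to 0.96 (0.85 to 1.08) in these higher-scored regions, an interval that holds both 1 and the value of all regions. Whether weakly called regions set the difference from H3K4me3 therefore stays open. A lower density of promoters on X than on autosomes would lower both ratios and was not tested, as no annotation in the same build was used here.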

How the results depend on the processing

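Of 77 values under alternative settings, 71 were unchanged and none reversed. Unchanged means the same direction and side of the threshold, or for counts a value within 1.5 times. Covered base pairs had no test, and there it means a change smaller than the SD of the single-list ratios. For scores and widths the threshold was that of permuted labels. Against circular shifts of the same setting, added after the values were seen, all 19 score and width alternatives also passed (largest permutation p = 0.0099), but the width difference was not above all shifts with all merged peaks (580 bp, shifted maximum 609 bp) and without CFP-1 RC03 (619 and 622 bp). The exceptions were as follows. The X to autosome density of H3K4me3 was 0.98 and not past the threshold. It was 0.90 (exact binomial p = 0.0052) among the 50% of peaks with the higher scores and 0.89 by covered base pairs. Over all 4 alternatives with a test its exact binomial p ran from 0.0052 to 0.786. The lower ratio by covered base pairs than by count means that H3K4me3 regions on X were shorter on average. Their median width was 567 bp on X and from 564 bp (V) to 705 bp (III) on autosomes. The cause of the lower ratio among the higher-scored peaks was not tested. By construction, the higher-scored peaks gave fewer regions, 4066 for CFP-1 and 4826 for H3K4me3, and merging the peaks of either list gave 12858 H3K4me3 regions. With 1 list left out, region numbers were 9216 to 9256 for CFP-1 and 11357 to 12343 for H3K4me3. Overlap shares with 1 list left out ran from 65.2 to 73.5% for CFP-1 on H3K4me3 and from 46.5 to 64.9% for H3K4me3 on CFP-1, the lowest without H3K4me3 RC03. The CFP-1 X ratio with 1 list left out was 0.91 to 0.94, and it was 0.95 (exact binomial p = 0.045) for all merged peaks. Requiring 50% of both intervals lowered the CFP-1 share to 10.8%, since H3K4me3 regions are wider than CFP-1 regions. Leaving out a list gives no value for the sharing between both samples. The labels do not state that a number marks a shared extract or day. As a replicate block, lists of the same number overlapped in 66.8% (CFP-1 on H3K4me3) and 49.6% (the reverse) of peaks, against 66.7% and 49.6% for lists of different numbers, and the RC03 to RC04 differences of both antibodies had a Spearman rho of -0.04 across 5427 shared regions. CpG density, transcript starts and gene lists were not run. Read depth is unknown, so the absence of a peak is not the absence of binding or of the mark.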

Other observations

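The tests in this part were chosen after the values had been seen, except those of neighbouring peaks and of single CFP-1 lists. CFP-1 was called at the tips of the chromosomes, which end in telomeric repeats. Both CFP-1 lists had a peak within 500 bp of all 6 left ends, where circular shifts gave means of 0.41 and 0.42 ends and at most 3 (permutation p = 0.001, the smallest the shifts can give). The median score of these peaks was 38.1 in RC03 and 15.5 in RC04. The H3K4me3 RC04 list also had a peak at 6 of 6 left ends (permutation p = 0.001), with a median score of 6.69. The H3K4me3 RC03 list had one at 1 left end (permutation p = 0.49). Peaks at the ends were thus not confined to CFP-1, and how reads were placed in repeats was not examined here. Over all 12 ends, both CFP-1 lists and the H3K4me3 RC04 list had a peak at each end, and the H3K4me3 RC03 list at 2. Shifted means ran from 0.84 to 1.32 ends. The right ends cannot be tested this way, because the last peak itself set the chromosome length. In the CFP-1 lists the running peak numbers skipped 19 values in RC03 and 1 in RC04, all between the last peak of IV and the first of V, while the H3K4me3 numbers had no gap.

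CFP-1 regions without any H3K4me3 peak numbered 1783, and 1482 of them (83.1%) were among the lower-scored 50% of CFP-1 regions. Only 19.8% (18.0 to 21.7%) had an H3K4me3 peak within 500 bp, under the bound of 50% set beforehand. For most of them this argues against the mark lying beside the CFP-1 interval and not under it. Shifts gave 17.7%, but that value also counts direct overlaps, which these regions were chosen not to have. Shifts of all CFP-1 regions overlapped such a peak directly in 11.8% of cases. The 17.7% is therefore no like-for-like chance level, and an excess of neighbouring peaks stays open. Weakly called CFP-1 regions stay open as a candidate explanation for most of them: in the highest decile 96.2% (94.6 to 97.4%) had an H3K4me3 peak, an interval that contains the 95% set as the bound. A low rank is not nearness to the peak caller's limit, however. The lowest decile held 365 of the 1783. CFP-1 regions without an H3K4me3 region had median scores of 8.32 in RC03 and 8.45 in RC04, against lowest peak scores of 1.41 and 1.31. The 29 regions without the mark in the highest decile are not weak calls.

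These 29 strong CFP-1 regions without H3K4me3 were concentrated on X. X held 19 of them (65.5%) but 94 of the 729 regions with the mark in the same decile (12.9%), an odds ratio of 12.8 (5.45 to 31.7). The pattern was first seen in the 15 regions without the mark that had the highest scores. Without these 15, X held 10 of the remaining 14, an odds ratio of 16.8 (4.72 to 74.8; Fisher's exact test, two-sided p = 1.2e-06), which argues against chance placement, although this split was made after the values of all 29 had been seen. Fewer H3K4me3 calls on X at any CFP-1 score is also argued against, since the odds ratio was 1.10 (0.92 to 1.31) in the lower-scored 50%, 1.41 (0.51 to 3.40) in decile 8 and 3.43 (1.42 to 7.92) in decile 9. The concentration on X was present in the highest decile of each CFP-1 list alone, ranked by that list's own scores. The odds ratios were 13.1 (6.10 to 29.5) in RC03 and 11.1 (5.21 to 24.8) in RC04. As a test of a single CFP-1 library as the source this adds little, because the 29 regions had to be called in both lists and were ranked by both. When this test was set, the scores of the first 15 regions in both lists had been seen, but not these odds ratios. The 19 regions spread from 0.41 to 17.5 Mb of X, had CFP-1 scores of 106.5 to 181.9 in RC03 and 100.6 to 171.3 in RC04, and lay a median of 6558 bp from the nearest H3K4me3 peak. After the 3 already named, the next 5 in order of score lay at 11093835 to 11094418, 5429099 to 5429866, 13700504 to 13701062, 1344855 to 1345299 and 6296187 to 6296785. The shortest gap to an H3K4me3 peak was 200 bp, at 17181194 to 17181548. Hypothetically, they may be sites where the dosage compensation complex, which binds X in hermaphrodite embryos, is recruited; the positions of those sites were not used here, and anti-GFP signal that does not depend on CFP-1 stays open because no list from a strain without GFP was analysed here.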
